A study of Mus musculus with 12 samples.

How the data were processed

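Total RNA from WT and Sgpp2-deficient C57BL6 mice on a normal or a high-fat diet was extracted with Trizol, and biotin-labelled cRNA was prepared from 4 µg of total RNA, per the labels' protocols, for 12 Affymetrix Mouse Genome 430 2.0 arrays, 3 in each of 4 groups. The deposited values are log2 RMA summaries, 1 per probe set and array. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a set. RMA and Partek 6.6 are named, per the submitters' processing notes; the order of steps, the options and the probe annotation are not given in the sources used here. The log2 scale of the values deposited by the authors was read from their range, 2.6 to 15.3, with array medians between 7.00 and 7.13. Because RMA equalises the distributions, a shift of most genes in 1 direction would be hidden, and probe sets near the lower end understate differences. Signal over the lower end takes the place of depth on arrays: between 75.9% and 77.3% of probe sets per array were above a log2 value of 5.

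Of 45101 probe sets, 64 were controls, 34945 named 1 gene symbol in the platform annotation, 932 named several and 9160 were not listed there, so that the last 2 kinds carry no gene name here. Of the probe sets with 1 symbol, 34741 matched the reference gene table (assembly GRCm38.p6) by Entrez identifier, and 0 symbols needed an update. Some genes of the fixed lists are not named in the probe table used here and were not analysed. The reference table was used for names and, through the start positions of genes, for their order along a chromosome. Distances were counted in genes and not in bases. Each of 18193 genes was represented by the probe set with the highest mean over all 12 arrays, chosen without regard to group, and 2956 genes that were not above a log2 value of 5 on at least 3 arrays were left out, which left 15237.

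Groups and replicate numbers were taken from the labels. Limma 3.58.1 in R 4.3.3 fitted 1 coefficient per group to all 12 arrays, with 8 residual degrees of freedom (11.08 after moderation), and 6 comparisons were read as contrasts: KO against WT on each diet and averaged over both, the high-fat against the normal diet in each genotype, and the interaction. The moderated test was two-sided and Benjamini-Hochberg adjustment was applied within a comparison over all genes tested, with a threshold of 0.05; every adjusted p of a gene is from this fit. The targeted gene was also tested by exact two-sided permutation. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 17 functional lists and separately over 19 lists of cell type markers, with the correlation estimated from the data and with fry as alternatives. Camera compares a list with the other genes, and fry asks whether the genes of a list move, on balance, 1 way. The 17 functional lists cover sphingolipid and S1P metabolism, the unfolded protein response, DNA replication and mitosis, G1 cyclins and CDK inhibitors, apoptosis, β-cell identity and secretion, genes disallowed in β-cells, cholesterol, fatty acid synthesis, fatty acid oxidation, inflammation, interferon response, oxidative phosphorylation, antioxidant response, immediate early genes, the circadian clock and extracellular matrix. Of 10 functional list calls over the 6 comparisons, 0 held with an estimated correlation and 0 with fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

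The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Per comparison the text names the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays do not overlap between the groups (within both diets for the average), makes up 10 with the smallest p where fewer pass, and adds up to 4 members of each list, first those past the threshold and then those with the smallest p. Symbols without a gene name are skipped. Enrichment of changed genes near Sgpp2 used Fisher's exact test within 200 protein-coding neighbours against other chromosomes; this test, and genes named for it outside the rule, were chosen after the values had been seen.

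Same-numbered KO arrays deviated together across the diets: the deviations of KO normal and KO high-fat arrays from their group means correlated with r = 0.29, 0.38 and 0.14 for numbers 1, 2 and 3, each over 0.1, and 1 of 6 ways of matching them did so at least as strongly. That 1 is the matching by number itself, the smallest share possible, so chance alone gives it in 1 of 6 cases. The same check was made for the other comparisons of 2 groups. The labels do not say what a number stands for, and the pairing therefore rests on these values. A paired fit of these groups, with the number as a block, made 0 calls for the diet in KO, as did the fit without it. For the average over diets the KO pairs were also fitted as a random block with limma's duplicateCorrelation, which gave a correlation of 0.368 within a pair.

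The scripts were tested on simulated data: 200 of 15237 genes were changed by a log2 value of 0.5, 1 or 2 on arrays drawn with the means and spreads measured here. At a change of 1, the fit recovered 86.6% of changed genes for KO against WT on the normal diet, 83.6% on the high-fat diet, 88.1% for the diet in WT, 86.6% for the diet in KO, 64.2% for the interaction and 94% for the average over diets. At a change of 0.5 the shares were 37.3%, 34.3%, 41.8%, 46.3%, 16.4% and 73.1%. Between 5 and 11 unchanged genes were called per comparison. With 200 genes and 1 list changed in each, the Benjamini-Hochberg cutoff was looser than in the real comparisons with 4 or 0 calls. The shares therefore do not show how many changed genes a comparison with so few calls recovers. A list shifted by 0.3 was recovered in all 6 comparisons, with 1 other list called in the high-fat comparison of genotypes. Each gene was drawn independently, so the simulated arrays hold no correlation between genes and no pairing of KO arrays. They therefore cannot show how often the list test makes false calls when genes are correlated.

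Alternatives covered the filter, the probe sets of a gene, the scaling between arrays, the replicate block, the variance model, array weights, the samples in the fit, the list test and leaving out each array. Those added after the data were seen leave out the neighbours of Sgpp2, fit the replicate block to the KO groups alone, and fit same-numbered KO arrays as a random block for the average over diets. The number of value columns not used was 0.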

Results

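RNA was measured on 12 Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample, from C57BL6 mice that were wild type (WT) or lacked Sgpp2 (KO) and were given a normal or a high-fat diet. Sgpp2 encodes sphingosine-1-phosphate phosphatase 2, an enzyme of the endoplasmic reticulum that removes the phosphate from the signalling lipid sphingosine-1-phosphate. The 4 groups held 3 arrays each. The sample labels named no tissue, and the title of the series named pancreatic islets, β-cell endoplasmic reticulum stress and proliferation. Islet hormones were among the brightest probe sets: over the 12 arrays the mean log2 value was 14.57 for Ins2 (insulin), 14.96 for Iapp, 14.40 for Gcg (glucagon), 14.27 for Sst (somatostatin) and 14.27 for Ppy. The acinar digestive enzymes Cpa1 and Cela2a had means of 13.97 and 13.95, the liver gene Alb 6.11 and the fat cell gene Adipoq 3.53. Of 18193 genes with a probe set of their own, 15237 were above the filter and were tested. The number of arrays limited the precision: the median standard error (SE) of a log2 difference between 2 groups was 0.12. The labels did not say that the arrays came from separate animals, so the p-values measure the spread between these samples, which may be technical.

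Arrays of 1 group correlated with r between 0.9912 and 0.9959. Component 1 of a principal component analysis held 27.1% of the variance and mostly followed genotype. The 6 KO arrays scored between 2.4 and 26.2 on it and 5 WT arrays between −21.1 and −7.5, while WT high-fat array 2 scored 6.5, among the KO arrays. KO high-fat array 3 had the highest score, 26.2. On component 2, with 20.3% of the variance, every array of the normal diet scored 5.6 or higher and every array of the high-fat diet −1.1 or lower.

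**Figure D1:**
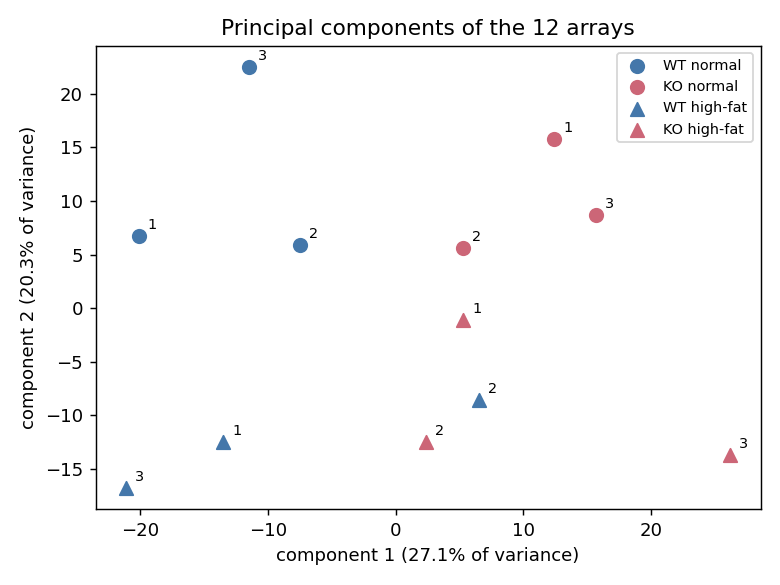
Principal component scores of the 12 arrays over the 15237 genes tested, component 1 (27.1% of variance) against component 2 (20.3%); each point is 1 array, blue for WT and red for KO, circles for the normal and triangles for the high-fat diet, with the replicate number beside it. WT high-fat array 2 lies at 6.5 on component 1, among the KO arrays.

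The targeted gene was read first. Sgpp2 was represented by 1 probe set and was lower in every KO array than in every WT array: the highest KO value was 11.17 and the lowest WT value 11.46. WT high-fat array 2 read 11.46, on the WT side. The KO mean was 72.7% of the WT mean over both diets (log2 difference −0.46, SE 0.05, exact two-sided permutation p = 0.00216, n = 6 per genotype; limma adjusted p = 0.00327). On the normal diet the difference was −0.50 (SE 0.07, adjusted p = 0.0263) and on the high-fat diet −0.42 (SE 0.07, adjusted p = 0.0824). The call on the normal diet was lost without WT normal array 1, 2 or 3 (adjusted p = 0.117, 0.0522 and 0.0992) or KO normal array 2 or 3 (0.0628 and 0.0935), and one on the high-fat diet was gained without WT high-fat array 2 (0.0383). With the replicate number as a block (paired) the adjusted p on the normal diet was 0.0538, and over all alternatives it ranged from 0.0087 to 0.117 there and from 0.0383 to 0.514 on the high-fat diet. Within 1 diet the exact permutation p was 0.1, the smallest that 3 arrays against 3 allow. The position of the probe set relative to the deleted part of the gene is not given in the sources used here, and a probe set outside the deletion would check nothing. The diet left Sgpp2 within the spread between arrays, with log2 differences of −0.06 in WT (adjusted p = 0.828) and 0.02 in KO (adjusted p = 0.991).

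**Figure D2:**
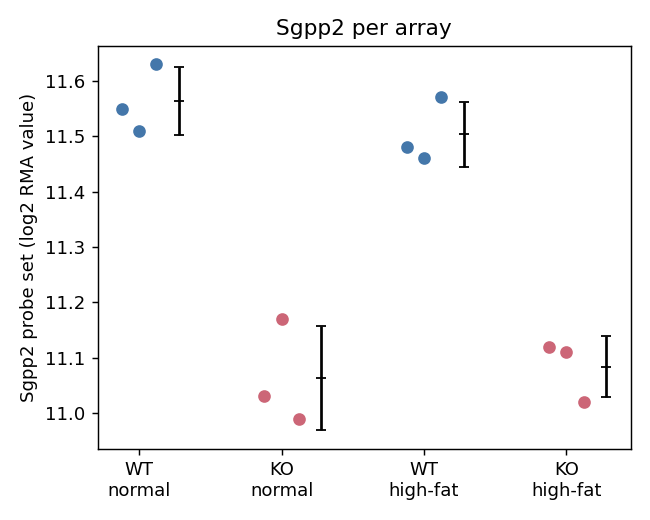
Sgpp2 probe set per array as log2 RMA value (vertical axis) in the 4 groups; each point is 1 array, and the bars are group means ± SD (n = 3). All KO arrays lie at or under 11.17 and all WT arrays at or over 11.46.

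The comparison of KO with WT on the normal diet asks which genes differed between the genotypes without the dietary load. Of the genes named in this paragraph, Col6a3, D2hgdh, Rab17, Stk25, Lrrfip1 and Speg lie within 200 protein-coding neighbours of Sgpp2. For these, an effect of the loss of Sgpp2 cannot be told apart from a chromosome segment carried along with the knockout allele. Among the genes that fell in KO were Col6a3, an α chain of collagen VI, which dropped by 2.81 on the log2 scale (SE 0.28, 7.03-fold, adjusted p = 0.00444), and D2hgdh, the mitochondrial D-2-hydroxyglutarate dehydrogenase, which dropped by 1.39 (SE 0.13, adjusted p = 0.00444). Rab17, a small GTPase of epithelial membrane traffic, fell by 1.75, the kinase Stk25 by 1.52 and Lrrfip1 by 1.25. Speg, a kinase of striated muscle, rose by 1.46 (SE 0.21, 2.75-fold, adjusted p = 0.0263), the serine protease Prss23 by 1.21, the GABA receptor subunit Gabrr2 by 1.13, the matrix protein Matn2 by 1.13 and the cyclic nucleotide phosphodiesterase Pde10a by 1.11. In all, 128 of 15237 genes changed, 73 up and 55 down, with a median size of 0.59 on the log2 scale, and 12 of them changed more than 2-fold.

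The further genes with the largest rises on the normal diet were Zfp982 (log2 1.23), the defensin Defa31 (1.10), Clca3a1 (0.99), the histone gene H3c4 (0.92) and Hspa14 (0.89). The further falls were in Kynu, the kynureninase of tryptophan breakdown (1.99-fold), the glycine receptor subunit Glra1 (log2 −0.93), Fa2h, the fatty acid hydroxylase of sphingolipid synthesis (−0.89), Inava (−0.88) and Acadl, the long-chain acyl-CoA dehydrogenase of fatty acid oxidation (−0.85, adjusted p = 0.0468). Other probe sets of these genes did not always move alike. The 3 further probe sets of Speg were higher by 0.66 to 1.13, and those of Lrrfip1 were lower by −0.79 and −1.56. The other probe set of D2hgdh differed by 0.15 (unadjusted p = 0.158) and that of Matn2 by 0.10 (unadjusted p = 0.535). Of the 128 genes, 76 had further probe sets above the filter, and in 31 of them another one moved the same way at an unadjusted p under 0.05 and in 9 another one moved the opposite way.

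Some members of the lists fixed beforehand changed on the normal diet, where 128 of all 15237 genes did. In the list of sphingolipid and S1P metabolism, with 34 measured members, Sgpp2 fell and no other member passed over all genes; adjusted over the list alone, 1 member rose and 2 fell. Sptlc2, a subunit of the enzyme that starts sphingolipid synthesis, differed by −0.42 (adjusted p = 0.063), and Sgpp1, the other S1P phosphatase gene, by 0.32 (adjusted p = 0.0939). Of 37 genes of the unfolded protein response, Sesn2, a stress-induced sestrin, fell by 0.66 (adjusted p = 0.0272), and 2 rose and 1 fell adjusted over the list alone. Of 32 genes of DNA replication and mitosis, Ccne2 (cyclin E2) rose by 0.67 and Mcm4, a subunit of the replicative helicase, by 0.57, although 26 members had lower means in KO and the list's median was −0.220. That direction rested on WT normal array 1: the median was 0.052 without it, and −0.343 and −0.356 without WT normal arrays 2 and 3. The other probe set of Mcm4 differed by −0.11 (unadjusted p = 0.328). Hadhb, of the mitochondrial trifunctional protein, rose by 0.57 while Acadl fell, the chemokine Cxcl1 rose by 0.69, and Cat (catalase) rose by 0.59. Iigp1, an interferon-induced GTPase, differed by 1.25 (adjusted p = 0.063). No functional list passed limma's camera test with its preset correlation; the smallest adjusted p was 0.108, for inflammation and NF-kB targets, with a median of 0.142, which became 0.091 without KO normal array 3, and 11 of 17 members higher; adjusted over the list alone, 3 of them rose and 1 fell.

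Lists of acinar markers, of T and NK markers and of sex-linked genes passed camera at its preset correlation on the normal diet. None of them passed with an estimated correlation or with fry (fry adjusted p = 0.157, 0.0707 and 0.0707). The sex-linked list holds Xist beside Y-linked genes, so its median has no single reading for sex. All 14 acinar markers had higher means in KO, with a median of 0.209 (camera adjusted p = 5.37e-06; adjusted p = 0.603 with an estimated correlation). All 8 markers of T and NK cells were higher, with a median of 0.212 (adjusted p = 0.0103; adjusted p = 0.401 with an estimated correlation), and the 4 sex-linked genes had a median of 0.465 (adjusted p = 0.0155; adjusted p = 0.401 with an estimated correlation). No single member of these lists passed over all genes; adjusted over the list alone, 1 T and NK marker and 2 sex-linked genes rose. The T and NK markers, with a median level of 5.49, lay close to the filter at 5: with the filter at 6 the call was lost (adjusted p = 0.316, range over alternatives 0.00389 to 0.401), as it was after cyclic loess (0.115) and without KO normal array 3 (0.05, not under the threshold), where the median was 0.123. With the mean of a gene's probe sets the sex-linked median was 0.122 and the call was lost (adjusted p = 0.448, range over alternatives 0.00391 to 0.448). It was lost too after cyclic loess (0.07), where the median was 0.488, and without KO normal array 1 (0.116), where the median was 0.292. The acinar markers, with a median level of 14.06, moved with the genotype beside each of the gene groups above.

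All 128 genes had values that did not overlap between the 3 KO and 3 WT arrays, as had 34.3% of all genes tested, against the 10% that chance gives. At an unadjusted p under 0.05 there were 3372 genes, against 762 by chance. The direction of the calls depended on the scaling between arrays: 57% of the calls were rises as reported, 77.6% of 98 calls after cyclic loess (76 up, 22 down) and 90.2% of 194 calls after centring each array on its median (175 up, 19 down). The count was 2, 4 and 3 without WT normal arrays 1, 2 and 3, 69, 5 and 3 without KO normal arrays 1, 2 and 3, 59, 223 and 30 without WT high-fat arrays 1, 2 and 3, and 72 and 67 without KO high-fat arrays 1 and 2.

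On the high-fat diet, 4 genes differed between KO and WT. Col6a3 fell by 2.05 (SE 0.28, 4.14-fold, adjusted p = 0.0489) and D2hgdh by 1.22 (SE 0.13, adjusted p = 0.0135), while Armc9 rose by 1.03 (SE 0.11, 2.05-fold, adjusted p = 0.0135) and Mcm4 by 0.84 (SE 0.10, adjusted p = 0.028). Genes of replication and mitosis lay higher in KO as a list: 27 of 32 had higher means and the median difference was 0.429, which became 0.083 without KO high-fat array 3. Genes of the interferon response and antigen presentation lay higher too, 19 of 23, with a median of 0.253, which became 0.125 without KO high-fat array 1. Both lists passed camera at its preset correlation and neither with an estimated correlation (adjusted p = 0.806 for each).

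Armc9 and D2hgdh each had further probe sets that did not follow. Of the 6 others of Armc9, 5 were lower in KO, by −0.18 to −0.78, and 1 was higher by 0.11. The other probe set of D2hgdh differed by 0.03 (unadjusted p = 0.759), and that of Mcm4 was higher by 0.25 (unadjusted p = 0.0331). The mean over all probe sets of Armc9 differed by −0.10, the opposite direction (adjusted p = 0.581, range over alternatives 0.00328 to 0.581). Over its alternatives the adjusted p ranged from 0.00185 to 0.348 for D2hgdh, from 0.0104 to 0.514 for Mcm4 and from 0.00707 to 0.505 for Col6a3. Of the genes with the next smallest p, none passed: Matn2 differed by 1.17 (adjusted p = 0.0513), Hpgd, which breaks down prostaglandins, by −0.81 (adjusted p = 0.0567), Ap1s3, of the AP-1 clathrin adaptor, by 2.12 (adjusted p = 0.0685), Speg by 1.36 (adjusted p = 0.0685), Zfp182 by 0.58 (adjusted p = 0.0712) and Stk25 by −1.54 (adjusted p = 0.0712).

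Among replication and mitosis genes on the high-fat diet, Mcm4 rose, also adjusted over the list alone. Ccne2 differed by 0.46 (adjusted p = 0.204), Nusap1 of the mitotic spindle by 0.80 (adjusted p = 0.384) and Rrm2, of ribonucleotide reductase, by 0.43 (adjusted p = 0.405). The list passed camera at its preset correlation (adjusted p = 9.21e-05), but not with an estimated correlation (adjusted p = 0.806), and without KO high-fat array 3 its median was 0.083 (adjusted p = 0.553, range over alternatives 9.2e-11 to 0.806), while without KO high-fat array 1 it was 0.660. KO high-fat array 3 had a list score of 0.908, the mean deviation of the 32 genes from their means over all arrays on the log2 scale, against −0.094 and 0.245 on the other KO high-fat arrays and −0.076 to 0.125 on the WT high-fat arrays. Of the interferon list no member passed over all genes or adjusted over the list alone; Ifit1 differed by 0.85 and Iigp1 by 0.83. That list had an adjusted p of 0.00019, and an adjusted p = 0.806 with an estimated correlation, and without KO high-fat array 1 the median was 0.125 and the adjusted p 0.0573 (range over alternatives 7.84e-06 to 0.806). Without WT high-fat array 3 its median was 0.117.

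The unfolded protein response list had a median of −0.079 in KO on the high-fat diet, with 24 of 37 members lower (adjusted p = 0.484). No member passed over all genes, and adjusted over the list alone 1 rose and 3 fell. Sesn2 differed by −0.52 (adjusted p = 0.108), Eif2ak3, which encodes the stress sensor PERK, by −0.43 (adjusted p = 0.191) and Herpud1, of endoplasmic reticulum-associated degradation, by −0.35 (adjusted p = 0.19). In the sphingolipid list Acer2, an alkaline ceramidase, differed by 0.39 (adjusted p = 0.206) and Degs1, the dihydroceramide desaturase, by 0.23 (adjusted p = 0.206); adjusted over the list alone, 1 member fell. The β-cell list of 32 genes had a median of −0.026, with camera's direction upward (adjusted p = 0.777); Neurod1 differed by 0.22 (adjusted p = 0.266) and Nkx6-1 by −0.33 (adjusted p = 0.369).

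In this comparison 2036 genes had an unadjusted p under 0.05, against 762 by chance, and 14.8% of genes tested did not overlap, against 10% by chance. The 4 calls were 2 rises and 2 falls; after cyclic loess there were 3 (1 up, 2 down) and after median centring 8 (5 up, 3 down). The count was 2 without WT normal array 1 or 2, KO normal array 2 or 3, WT high-fat array 1 or KO high-fat array 3, 1 without WT high-fat array 3, 0 without KO high-fat array 2 and 272 without WT high-fat array 2.

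The genotype differences of both diets went mostly the same way. Of the 128 genes called on the normal diet, 116 had the same sign on the high-fat diet, where their median size along that direction was 0.341 against 0.59, and all 4 genes called on the high-fat diet, Col6a3, D2hgdh, Armc9 and Mcm4, were also called on the normal diet. Across all 15237 genes the differences measured on the separate sets of 6 arrays correlated with Pearson r = 0.467 and Spearman rho = 0.494. Genes are not independent replicates, and no p is given. The KO arrays of these sets are not known to be separate samples, since those of 1 number deviated together, which could raise the agreement.

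Averaged over both diets, with 6 arrays against 6, 963 genes changed, 503 up and 460 down, most by little: the median size was 0.349 on the log2 scale and 15 genes changed more than 2-fold. Same-numbered KO arrays deviated together across the diets, so that the 6 KO arrays are not known to be 6 separate samples: with these pairs as a random block 352 genes changed, 233 up and 119 down, all of them among the 963, and with the replicate number as a block in every group 524 changed. Ap1s3 rose by 1.77 (SE 0.22, 3.42-fold, adjusted p = 0.00388), Speg by 1.41 (SE 0.15, adjusted p = 0.00207), Zfp982 by 1.27, Matn2 by 1.15 and Prss23 by 1.13. Col6a3 fell by 2.43 (SE 0.20, 5.39-fold, adjusted p = 0.000568), Stk25 by 1.53, Rab17 by 1.36, D2hgdh by 1.30 (SE 0.09, adjusted p = 0.000377) and Lrrfip1 by 1.04. These and the next genes were ranked among those whose arrays do not overlap between the genotypes within both diets. By that rule Klhl30 (1.63) and Mfsd9 (−1.32), which passed as well, are not among them. The remaining genes with the largest rises under it were Cttnbp2 (log2 1.12), Iigp1 (1.04), the cadherin Cdh7 (0.98), the contactin Cntn3 (0.94) and Defa31 (0.90). The remaining falls under it were in Acadl (−0.74), Cap1, a regulator of actin (−0.72), the clock kinase Csnk1e (−0.70), the protease Tmprss2 (−0.68) and Zfp941 (−0.64). Further probe sets of Cdh7 (−0.32 and −0.22), Cntn3 (−0.30) and Cttnbp2 (−0.12) lay on the other side of 0, and those of Cap1 (−0.68) and Tmprss2 (−0.43 and −0.25) on the same side.

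Of the 46 genes named over both diets that passed, 16 did not pass with same-numbered KO arrays as a random block (paired): Iigp1, Cap1, Csnk1e, Sptlc2, Sgpp1, Canx, Casp8, Mcl1, Stard4, Nfkb2, Ifit1, Atp5o, Pecam1, Kdr, Pdgfrb and Vil1, with adjusted p between 0.0518 and 0.0941.

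Genes of sphingolipid metabolism moved in both directions. Sgpp1 rose by 0.29 (adjusted p = 0.0267) and Acer2 by 0.37 (adjusted p = 0.0285), while Sptlc2 fell by 0.30 (adjusted p = 0.0285) and Sgpp2 by 0.46. Of the 34 members 3 rose and 2 fell over all genes, and 4 rose and 2 fell adjusted over the list alone. The list's median was −0.051 while camera's direction was upward (adjusted p = 0.769). A further probe set of Sgpp1 was higher by 0.51 and another differed by −0.07 (unadjusted p = 0.482). Sptlc2 had further probe sets at −0.25 and 0.13.

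Of the 37 unfolded protein response genes, Derl1, of endoplasmic reticulum-associated degradation, rose by 0.30, the chaperone Canx (calnexin) rose by 0.19 and Sesn2 fell by 0.59 (adjusted p = 0.0034); the median was 0.011, the mean −0.045 and camera's direction upward (adjusted p = 0.769). The other probe set of Sesn2 differed by −0.11 (unadjusted p = 0.244), and the 3 others of Derl1 by −0.04 to −0.12. Of 32 replication and mitosis genes, Mcm4 rose by 0.71 and Ccne2 by 0.56 (list median 0.068, adjusted p = 0.216). The other probe set of Mcm4 differed by 0.07 (unadjusted p = 0.344). Further probe sets of Hadhb differed by −0.13 and by less than 0.01, that of Gclm by 0.03, that of Cxcl1 by 0.07, that of Nfkb2 by −0.09 and that of Atp5o by −0.09, while those of Cat, Acaa1a and Iigp1 were higher by 0.42, 0.37 and 0.54. In fatty acid oxidation Hadhb rose by 0.54 and Acaa1a, a peroxisomal thiolase, by 0.36, while Acadl fell; adjusted over the list alone, 2 of 24 rose and 5 fell (median −0.121, adjusted p = 0.769). Cat rose by 0.48 and Gclm, which makes glutathione, fell by 0.46 among 22 antioxidant genes; adjusted over the list alone, 1 rose and 2 fell (median −0.084, adjusted p = 0.769). Cxcl1 rose by 0.51 and Nfkb2 by 0.30 among 17 inflammation genes, where 3 rose adjusted over the list alone (median 0.078, adjusted p = 0.107). Casp8 fell by 0.24 and the survival factor Mcl1 rose by 0.24 among 19 apoptosis genes; adjusted over the list alone, 1 rose and 2 fell (median −0.009, adjusted p = 0.881, direction upward). Stard4, a sterol carrier, fell by 0.32 among 16 cholesterol genes (median −0.053, adjusted p = 0.673). Atp5o rose by 0.19 among 28 genes of oxidative phosphorylation (median −0.057, adjusted p = 0.497), and Col6a3 was the member of the 21 matrix genes that fell (median −0.020, adjusted p = 0.881, direction upward). Acadl, Casp8 and Col6a3 lie within 200 protein-coding neighbours of Sgpp2, as described below, so their differences need not follow from its loss.

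Iigp1 and Ifit1 rose by 1.04 and 0.76 among 23 interferon genes, and 4 members rose adjusted over the list alone. The median was 0.171 with 17 members higher, and the list passed camera (adjusted p = 0.00676; adjusted p = 0.944 with an estimated correlation). The median was 0.105 without KO normal array 1, 0.088 without WT high-fat array 3 and 0.082 without KO high-fat array 1. Limma called no member of 6 lists. Their medians were −0.057 for the 32 β-cell identity and secretion genes (adjusted p = 0.881), −0.068 for the 16 G1 cyclins and CDK inhibitors (adjusted p = 0.881, 1 rise and 1 fall adjusted over the list alone), −0.148 for the 14 genes disallowed in β-cells (adjusted p = 0.769; −0.022 without WT normal array 3 and −0.066 without KO high-fat array 2), −0.106 for the 20 genes of fatty acid and triglyceride synthesis (adjusted p = 0.271), −0.119 for the 17 immediate early genes (adjusted p = 0.769; −0.078 without WT normal array 1) and −0.145 for the 17 clock genes (adjusted p = 0.918, direction upward; −0.079 without WT high-fat array 3 and −0.062 without KO high-fat array 3). Among β-cell genes the transcription factors Nkx6-1 and Foxa2 differed by −0.36 (adjusted p = 0.0607) and −0.26 (adjusted p = 0.0599).

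Among cell type markers, endothelial genes lay lower in KO, 10 of 11, with a median of −0.211 (camera adjusted p = 0.044; adjusted p = 0.614 with an estimated correlation). Pecam1 fell by 0.50 and Kdr, the VEGF receptor 2, fell by 0.23; 3 fell adjusted over the list alone. All 14 acinar markers lay higher (median 0.135, adjusted p = 0.000139; adjusted p = 0.752 with an estimated correlation), as did all 8 T and NK markers (median 0.118, adjusted p = 0.04; adjusted p = 0.614 with an estimated correlation). After cyclic loess, neither list passed (adjusted p = 0.0851 and 0.17; range over alternatives 1.23e-06 to 0.752 for the acinar and 0.0269 to 0.614 for the T and NK list). The Y-linked genes Uty and Kdm5d rose by 0.55 and 0.45, although the further probe sets of Kdm5d were lower by −0.24 and −0.08 and those of Uty read −0.32, 0.42 and 0.90, and the sex-linked list passed (median 0.299, adjusted p = 0.04; adjusted p = 0.614 with an estimated correlation). Eif2s3y read between 11.89 and 12.52 on every array and Xist between 5.01 and 6.74. With the mean of a gene's probe sets the sex-linked median was 0.044 and the call was lost (adjusted p = 0.292). It was lost too, at medians that did not shrink, after cyclic loess (0.0851, median 0.34) and median centring (0.0861, median 0.379). The endothelial call was lost with the filter at 6 (0.0941), with the mean of a gene's probe sets (0.0722) and after cyclic loess (0.0851). The T and NK call was lost with the filter at 6 (0.378, median 0.168), with the mean of a gene's probe sets (0.121, median 0.099) and after median centring (0.0531, median 0.198). The endothelial call was also lost without WT normal array 3 (adjusted p = 0.115), KO normal array 1 (0.0779) or 2 (0.0629), WT high-fat array 1 (0.071) or 2 (0.125), or KO high-fat array 1 (0.0623) or 2 (0.081), with a range over alternatives of 0.0165 to 0.614. The sex-linked call was also lost without WT normal array 3 (0.0523), KO normal array 1 (0.0779), WT high-fat array 1 (0.071) or KO high-fat array 1 (0.0623), with a range of 0.0067 to 0.614. The T and NK call was also lost without WT normal array 3 (0.0523), KO normal array 3 (0.0883, median 0.075), WT high-fat array 2 (0.0924) or 3 (0.0589), or KO high-fat array 1 (0.0985). Of the control measures of RNA integrity, the gap between the 3′ and 5′ probe sets of pyruvate carboxylase differed by −0.36 on the log2 scale and did not pass after adjustment (exact permutation p = 0.0195, adjusted over 6 control measures 0.0584), and those of β-actin, Gapdh and the transferrin receptor differed by 0.02, −0.10 and 0.05 (exact p = 0.749, 0.446 and 0.643).

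Of the 963 genes, 682 did not overlap between genotypes within both diets, as did 1132 of all genes tested. The rises made up 52.2% of the calls as reported, 70% of 882 calls after cyclic loess (617 up, 265 down) and 83.8% of 1063 calls after median centring (891 up, 172 down). Of 618 called genes with further probe sets above the filter, another probe set moved the same way in 245 and the opposite way in 169 at an unadjusted p under 0.05. The count was 255 and 324 without WT normal arrays 1 and 3, 480 and 260 without KO normal arrays 2 and 3, 369, 2500 and 311 without WT high-fat arrays 1, 2 and 3, and 594 and 392 without KO high-fat arrays 2 and 3.

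Several of these genes lie close together. In the gene order of the assembly GRCm38.p6, Speg, Ap1s3, Armc9, Col6a3, Rab17, Lrrfip1, Stk25 and D2hgdh are all within 200 protein-coding neighbours of Sgpp2. Acadl, Casp8, Cdh7 and Vil1 are as well. Within that distance 41 of 279 genes (14.7%) changed with genotype over both diets, 18 up and 23 down, against 826 of 13396 (6.17%) on other chromosomes (odds ratio 2.62, 95% interval 1.82 to 3.69, Fisher's exact p = 5.71e-07). For changes over 2-fold the counts were 8 of 279 and 6 of 13396. Of the 20 smallest p, 7 belonged to these neighbours or Sgpp2. This comparison was chosen after the values had been seen. The 3 calls Col6a3, D2hgdh and Armc9 on the high-fat diet lay within the same distance. Within 50, 100 and 400 neighbours the odds ratios over both diets were 3.33 (1.72 to 6.03), 3.04 (1.87 to 4.78) and 1.86 (1.4 to 2.46). On the same chromosome beyond 400 it was 1.46 (0.905 to 2.27). Of these distances, 200 gave the smallest p. Fisher's test takes genes as independent, which neighbours read on the same arrays need not be. Its p may therefore be too small and its intervals too narrow.

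**Figure D3:**
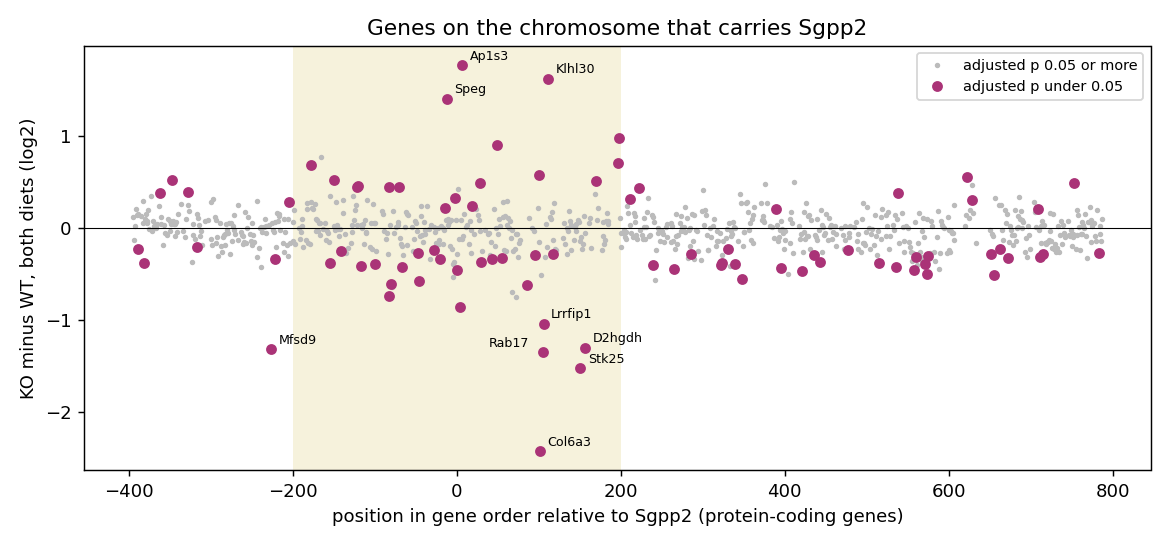
KO minus WT over both diets (log2, vertical axis) for genes on the chromosome that carries Sgpp2, by position in gene order relative to Sgpp2 (horizontal axis, protein-coding genes); purple points passed an adjusted p of 0.05, those over 2-fold are named, and the shaded band marks 200 neighbours on either side. Of the genes in the band, 41 of 279 passed.

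The high-fat diet in WT mice changed 12 genes. Reg2, a secreted regenerating protein of the pancreas, fell by 4.19 on the log2 scale (SE 0.63, 18.2-fold, adjusted p = 0.0444), Fam163a by 1.36, Rasgrp1, an activator of Ras, by 1.35 and Pnma1 by 1.17. Slc10a6, a transporter of steroid sulfates, rose by 1.48 (SE 0.17, 2.80-fold, adjusted p = 0.0325), the embryonic globin Hbb-bh1 by 0.87 and the corepressor Tle1 by 0.69. Genes of the unfolded protein response lay slightly higher on the high-fat diet, 34 of 37, with a median of 0.130, and matrix genes lay lower, 17 of 21, with a median of −0.254. Both lists passed camera at its preset correlation and neither with an estimated correlation (adjusted p = 0.499 and 0.771).

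The remaining falls in WT were in Tmem40 (−0.90), the calcium-binding Tesc (−0.83), Hmgb3 (−0.78), the hypoxia-induced mitochondrial protein Higd1a (−0.73) and Haus1, of the augmin complex of the spindle (−0.63). Further probe sets of Tesc, Higd1a and Tle1 moved the same way, by −0.78, by −0.56 and −0.53, and by 0.50. The other probe set of Rasgrp1 differed by −0.06 (unadjusted p = 0.753). Of the list members, the stress genes Herpud1 (0.51, adjusted p = 0.101), Eif2ak3 (0.44, adjusted p = 0.212), Trib3 (0.83, adjusted p = 0.284) and Dnajb9 (0.20, adjusted p = 0.286) did not pass over all genes, and adjusted over the list alone 1 rose. The unfolded protein response list passed camera (adjusted p = 7.76e-07; adjusted p = 0.499 with an estimated correlation), and its median stayed between 0.093 and 0.171 with each array left out in turn. The acinar markers, which make much secretory protein, had a median of −0.022 in the same comparison.

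Of the matrix genes, Col6a3 differed by −1.01 (adjusted p = 0.212), Col1a1 by −0.98 (adjusted p = 0.319), Mmp14, a membrane-bound matrix protease, by −0.51 (adjusted p = 0.182) and Col4a1 by −0.26 (adjusted p = 0.319). Adjusted over the list alone 2 fell, and the list passed camera (adjusted p = 0.00108; adjusted p = 0.771 with an estimated correlation). Markers of fibroblasts, stellate cells and pericytes, which share collagen genes with this list, had a median of −0.413 (adjusted p = 0.0926; −0.739 and −0.173 without WT normal arrays 2 and 3), and those of neurons and Schwann cells −0.376, lower in 6 of 6 (adjusted p = 0.0761; −0.569 and −0.133 without the same arrays). The B cell marker Ms4a1 differed by 0.93 (adjusted p = 0.0545), the cell cycle inhibitor Cdkn1a by 0.75 (adjusted p = 0.122), the S1P receptor S1pr1 by 0.44 (adjusted p = 0.284), the β-cell factor Pdx1 by −0.23 (adjusted p = 0.288) and Tph2 by −1.14 (adjusted p = 0.174). The coactivator Ppargc1a differed by 1.25 (adjusted p = 0.101).

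The 12 calls, 3 up and 9 down, did not overlap between diets, as 15.8% of genes tested, against 10% by chance; 1695 genes had an unadjusted p under 0.05 against 762 by chance. After cyclic loess there were 18 calls (7 up, 11 down) and after median centring 17 (7 up, 10 down), so that 38.9% and 41.2% were rises against 25%. The count was 0 without WT normal array 1 or 3, KO normal array 2 or 3, or WT high-fat array 1 or 2, 2 without WT normal array 2 or WT high-fat array 3, and 6 without KO high-fat array 1.

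In KO mice no gene passed the test of the high-fat diet with limma: the smallest adjusted p was 0.306, and 1173 genes had an unadjusted p under 0.05 against 762 by chance. The genes with the smallest p included Cyp2r1, a vitamin D 25-hydroxylase (log2 0.68), Clvs2 (0.86), Npr3, the natriuretic peptide clearance receptor (−0.91), Rhoj (0.44), Inpp4b (0.60), the chemokine Cxcl14 (−0.70), Mest (−0.40), Klk6 (−0.66), Gabrr2 (−0.88) and Pik3cg (0.63), all with an adjusted p of 0.306. Replication and mitosis genes had a median of 0.522, with 28 of 32 higher on the high-fat diet, and all 14 acinar markers lay lower, with a median of −0.167. Both lists passed camera at its preset correlation and neither with an estimated correlation (adjusted p = 0.582 and 0.793). Without moderation of the variance, with trend and robust moderation and with array weights the count of changed genes was 0 as well.

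The mitotic genes Tpx2 (log2 1.54, adjusted p = 0.452), Cdc20 (1.42, adjusted p = 0.409), Ube2c (1.35, adjusted p = 0.408) and Ccnb2 (1.23, adjusted p = 0.494) had the smallest p of their list, of which 3 rose adjusted over the list alone. The list passed camera (adjusted p = 1.21e-11; adjusted p = 0.582 with an estimated correlation); KO high-fat array 3 had its highest score, 0.908, and the median was 0.316 without that array and 0.794 without KO high-fat array 1. Interferon genes lay higher, 21 of 23, with a median of 0.152 (adjusted p = 0.00051; adjusted p = 0.582 with an estimated correlation). Rsad2 differed by 0.49 (adjusted p = 0.516) and Usp18 by 0.31 (adjusted p = 0.503), and without KO high-fat array 1 the list's median was 0.081 and its adjusted p 0.163 (range over alternatives 1.72e-05 to 0.631). Its median was 0.240 without KO normal array 3 and 0.258 without KO high-fat array 3. The acinar list passed (adjusted p = 1.03e-05; adjusted p = 0.793 with an estimated correlation), with Reg1 at −0.39 and Cela2a at −0.32. The unfolded protein response list had a median of 0.031, with 22 of 37 higher (adjusted p = 0.248). Of the 12 genes called for the diet in WT, 11 had the same sign in KO, at a median size of 0.367 against 0.883, and across genes the diet differences of WT and KO correlated with r = 0.418 and rho = 0.304. The share of genes that did not overlap was 13.0%, against 10% by chance.

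**Figure D4:**
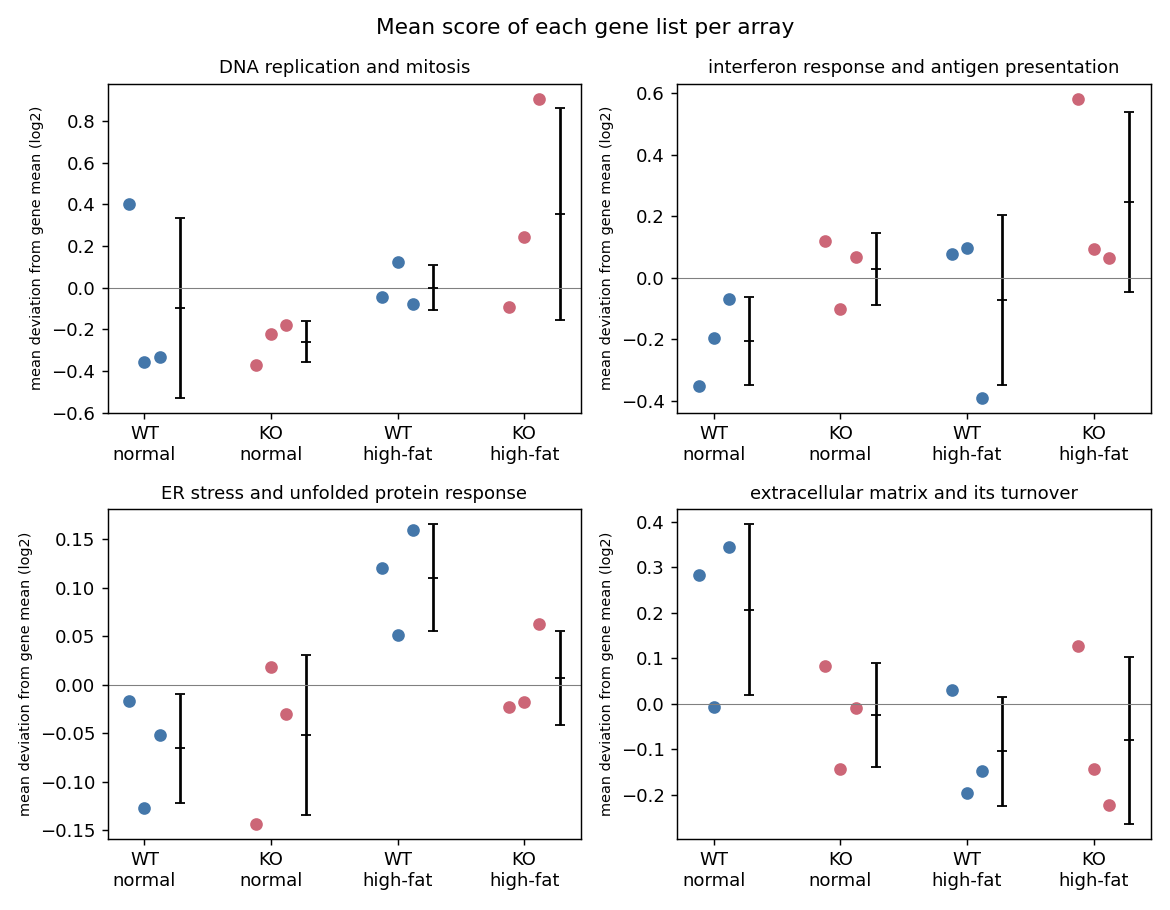
Mean deviation of a list's genes from their means over the 12 arrays (log2, vertical axis) per array in the 4 groups, for 4 gene lists; each point is 1 array, blue for WT and red for KO, and bars are group means ± SD (n = 3). KO high-fat array 3 reads 0.908 for replication and mitosis.

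The interaction asks whether the genotype difference depended on the diet. No gene passed with limma: the smallest adjusted p was 0.722, and 758 genes had an unadjusted p under 0.05 where chance gives 762. Haus1 (log2 0.71), Wnt5b (1.01), Cyp2r1 (0.72), Trdmt1 (0.68) and Mylip (0.49) had the smallest p among genes whose KO minus WT difference was higher on the high-fat diet, and Itga10 (−0.79), Ahsa2 (−0.71), Gabrr2 (−1.11) and Slc25a45 (−1.11) among those where it was lower, all with an adjusted p of 0.722. The difference in Sgpp2 itself was 0.08 (adjusted p = 0.998). Without moderation of the variance, with trend and robust moderation and with array weights the count of changed genes was 0 as well.

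Of the lists, replication and mitosis genes had a higher KO minus WT difference on the high-fat diet, 29 of 32, by a median of 0.548 (camera adjusted p = 2.2e-05; adjusted p = 0.849 with an estimated correlation), among them Ube2c (1.06) and Aurkb (0.96). Unfolded protein response genes had a lower one, 27 of 37, by a median of −0.093 (adjusted p = 0.00207; adjusted p = 0.849 with an estimated correlation), among them Herpud1 (−0.33), Manf (−0.28) and Dnajb11 (−0.27). Matrix genes had a higher one, 18 of 21, by a median of 0.237 (adjusted p = 0.00864; adjusted p = 0.849 with an estimated correlation), among them Mmp14 (0.47) and Col4a2 (0.29). None of these members passed over all genes or adjusted over its list alone. The acinar markers had a lower difference, 12 of 14, with a median of −0.141 (adjusted p = 0.00277; adjusted p = 0.714 with an estimated correlation), as had all 5 B and plasma cell markers, with a median of −0.467 (adjusted p = 0.0208; adjusted p = 0.619 with an estimated correlation). Calls of these lists were lost without single arrays. The mitosis call was lost without KO high-fat array 3 (adjusted p = 0.181, median 0.226), and the median was 0.245 without WT normal array 1. The unfolded protein response call was lost without KO normal array 2 (0.0906, median −0.036), and its median was −0.041 and −0.056 without WT high-fat arrays 1 and 3 and −0.054 without KO high-fat array 1. The ranges over alternatives were 1.66e-13 to 0.866 and 6.45e-05 to 0.866. The matrix call was lost without WT normal array 3 (0.206), KO normal array 2 (0.0906), WT high-fat array 2 (0.0787) or KO high-fat array 1 (0.158, median 0.157), and the acinar call without WT normal array 1 (0.125, median −0.091) or WT high-fat array 1 (0.0852), with ranges of 2.17e-05 to 0.866 and 2.17e-06 to 0.733. The B and plasma cell call was lost without WT normal array 1 (0.061) or 3 (0.0702), WT high-fat array 2 (0.0537, median −0.247) or 3 (0.0763, median −0.308), or KO high-fat array 3 (0.249), with a range of 0.00109 to 0.681. It was lost too with the filter at 6 (0.215), with the mean of a gene's probe sets (0.0848), after cyclic loess (0.0981) and with array weights (0.133). The acinar median was −0.219 without WT high-fat array 2 and the B and plasma cell median −0.291 without WT normal array 2. Adjusted over the list alone, 1 B and plasma cell marker fell.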

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

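The tests of the gene order around Sgpp2, of its neighbours in the other comparisons, of immune markers, of acinar markers and of the splits that keep KO arrays of 1 number together were chosen only after the result they bear on had been seen.

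Genes that changed with genotype lay near Sgpp2, with an odds ratio of 2.62 (95% interval 1.82 to 3.69) for the 279 genes within 200 neighbours against other chromosomes. The intervals in this paragraph take genes as independent and may be too narrow. For changes over 2-fold at an unadjusted p under 0.05, a rate among these neighbours as high in any comparison as for genotype is argued against: 8 changed with genotype (odds ratio 56.4, interval 17.7 to 183), against 0 with the diet averaged over genotypes (odds ratio 0, upper bound 6.09), 3 with the diet in WT (2.84, interval 0.564 to 8.88), 1 with the diet in KO (0.941, upper bound 5.53) and 1 in the interaction (1.46, upper bound 8.77). For the calls of any size such a rate stays open: with as many genes of smallest p taken from each comparison, the odds ratio for the diet averaged over genotypes was 1.42 (0.89 to 2.18) and for the diet in WT 1.18 (0.705 to 1.87), intervals that overlap the one for genotype, although those for the diet in KO, 0.937 (0.525 to 1.56), and the interaction, 0.632 (0.31 to 1.16), lay below it. Sequence variants under single probe sets stay open too: another probe set moved the same way for 10 of 19 called neighbours that had one and for 217 of 556 called genes elsewhere (odds ratio 1.73, interval 0.622 to 4.91), and another moved the opposite way for 7 of the 19 and 157 of the 556 (1.48, 0.485 to 4.17), too few genes to decide. A candidate explanation that goes with the values is a chromosome segment carried along with the knockout allele, whose alleles may differ in expression from those of the WT mice, while an effect of the loss of Sgpp2 itself on its neighbours is untested, since every KO array carries both.

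Replication and mitosis genes lay higher in KO than in WT on the high-fat diet, by a median of 0.429. A single array goes with the values: without KO high-fat array 3 the median was 0.083, against 0.316 to 0.660 without each of the others. More immune cells in the KO samples stay open: the 23 markers of B cells, T cells and macrophages had a median of −0.134 (SE 0.056), but it was −0.034 without KO high-fat array 3, −0.064 without WT high-fat array 1 and −0.229 without KO high-fat array 1. The kinds of cell also went apart, with medians of −0.288 for 5 B and plasma cell markers and −0.222 for 10 macrophage markers (−0.105 and −0.056 without KO high-fat array 3) and 0.057 (SE 0.054) for 8 T and NK markers, 7 of them higher. Whether that sample differed in biology or in handling cannot be read from these arrays, and the loss of Sgpp2 under the high-fat diet stays open as an untested explanation of the rest.

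Unfolded protein response genes lay higher on the high-fat diet in WT, by a median of 0.130. A single array is argued against: the lowest median with 1 array left out was 0.093, without WT high-fat array 1. More acinar tissue in the high-fat samples stays open: of the 14 acinar markers 4 were higher and 10 lower, and their median of −0.022 (SE 0.062) differed from 0 by less than its error. The diet, which the design names, stays among the open explanations and was not tested apart from these.

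The KO minus WT difference was larger or smaller on the high-fat diet than on the normal diet for 5 lists. The median of that change was 0.548 for replication and mitosis, −0.093 for the unfolded protein response, 0.237 for extracellular matrix, −0.141 for acinar markers and −0.467 for B and plasma cell markers; each passed camera at its preset correlation and none with an estimated correlation (adjusted p = 0.849, 0.849, 0.849, 0.714 and 0.619). Outside the gene comparisons, 222 of 6737 probe sets that carry no single gene name changed between genotypes over both diets, 125 up and 97 down, with limma. The control probe set for the mouse B2 repeat was higher in KO than in WT by 0.36 on the log2 scale (SD 0.18 in KO and 0.07 in WT, n = 6 each, exact permutation p = 0.00433, adjusted over 6 control measures 0.026), and the lowest KO value, 8.69, was under the highest WT value, 8.73.

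Other splits of the arrays into groups of the same sizes were counted for each comparison. Over both diets, 2 of 100 splits gave as many calls as the real one, itself included. The real split gave 963 and the highest other 2330, for the split that exchanges WT high-fat array 2 with KO high-fat array 2. The cause of that count was not tested, and these 2 arrays read Sgpp2 on the sides of their labels (11.46 and 11.11). That split parts the KO arrays numbered 2, and same-numbered KO arrays deviated together. Of the 28 splits that keep the KO arrays of each number together, as the real one does, 1 gave as many calls, the real one, and the highest other count was 220. Both shares are under 0.05, which argues against chance as far as the arrays, or the pairs of KO arrays, are separate samples. They do not exclude it. In the first set another split gave more calls than the real one. In the second, 1 of 28 is the smallest share possible, and the pairing was read from these same values. With these pairs as a random block the count was 352. For the interaction the real count was 0, which all 100 splits reach by construction, so the splits say nothing about it; the highest other count was 963, from the split that exchanges the genotypes of the high-fat arrays and so turns the interaction into the genotype difference. For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real and highest other counts were 128 and 0 for KO against WT on the normal diet (1 split as high), 4 and 0 on the high-fat diet (1 split), 12 and 0 for the diet in WT (1 split), and 0 and 2 for the diet in KO, where all 10 splits reach a count of 0 by construction.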

How the results depend on the processing

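The settings that leave out the neighbours of Sgpp2 and that block the KO arrays alone by their number were chosen only after the result had been seen. The number of changed genes depended on the setting more than the direction of single genes. With every probe set on its own the counts were 546 on the normal diet, 81 on the high-fat diet and 2896 over both, with more tests made. With the mean of a gene's probe sets, 69 genes were called on the normal diet, 49 of them shared. Reversed with that mean were Armc9 on the high-fat diet (−0.10), Cdkn1b (−0.09) and Cox6c (0) on the normal diet, Derl1 (−0.03) and Kdm5d (−0.03) on the high-fat diet, and Cdkn1b (−0.09), Fdft1 (0.05) and Cpt1a (0.34) over both; the probe sets of these genes differed in direction. Median centring gave 194 and 8 calls on the normal and the high-fat diet. Trend and robust moderation gave 336 and 63 calls and 24 for the diet in WT; no moderation gave 83, 0 and 0; array weights gave 1175 on the normal diet, 7 on the high-fat diet and 1840 over both. Fitting only the groups compared, with fewer samples to estimate the spread, gave 6, 0 and 1. Where no construction is named, the cause was not tested. Of 10 functional list calls, 0 held with an estimated correlation and 0 with fry. Leaving out Sgpp2 and its neighbours left 0 calls on the high-fat diet, 99 on the normal diet and 905 over both. That took out 3, 11 and 42 called genes, and 1, 18 and 16 others were lost with their fold unchanged, among them Mcm4 on the high-fat diet (0.84, adjusted p = 0.0825, range over alternatives 0.0104 to 0.514).

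With the replicate number as a block (a paired fit), 9 genes were called on the normal diet, 2 on the high-fat diet, 0 for the diet in WT and 524 over both. Same-numbered arrays did not deviate together in the comparisons of genotype (r = −0.26, −0.10 and 0.05 on the normal diet, −0.05, −0.51 and −0.35 on the high-fat diet) or of the diet in WT (0.05, 0.10 and −0.16), so that these values give no sign of a pairing there. In KO, where same-numbered arrays deviated together, a pairing rests on these values alone, and chance can give such a match. The block changed no call for the diet there, where the count was 0 without it. With these KO pairs as a random block 352 genes were called over both diets, all among the 963, and of 46 named genes 30 were kept and 16 lost.

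Leaving out 1 array at a time gave 2 to 223 calls on the normal diet, 0 to 272 on the high-fat diet, 0 to 11 for the diet in WT and 255 to 2500 over both. The 223, 272 and 2500 calls came without WT high-fat array 2, the 2 and 255 calls without WT normal array 1 and the 11 calls without KO normal array 1; the cause was not tested. The difference of Sgpp2 between the diets in KO lay between −0.01, without KO normal array 3, and 0.07, without KO normal array 2, and was reversed in the former. The KO against WT difference of Sgpp2 over both diets lay between −0.49 and −0.44. For the diet in KO and for the interaction the count was 0 in every setting run. Of named genes past the threshold, 617 results were kept and 463 lost with 1 array left out, and 738 were kept and 190 lost in the other settings; of called lists, 206 were kept and 34 lost, and 163 and 57. On arrays, signal near the lower end of 2.6 limits differences: without a filter on low values 119 genes were called on the normal diet, 114 of them shared.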

Other observations

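The lists and genes described here were picked after their values were seen, and no test was added for them. Markers of macrophages had a median KO minus WT difference of −0.234 over both diets, with 8 of 10 lower (camera adjusted p = 0.365), and the complement gene C1qa, made by macrophages, differed by −0.33 (adjusted p = 0.053). On the high-fat diet 9 of 10 macrophage markers lay lower in KO (median −0.222, adjusted p = 0.189; −0.122 without WT high-fat array 3 and −0.056 without KO high-fat array 3), as did 6 of 7 ductal markers (median −0.242, adjusted p = 0.189; −0.122 without KO high-fat array 3). The markers of delta, PP and epsilon cells, which include genes other than hormones, had a median of −0.091 over both diets, with 6 of 7 lower (adjusted p = 0.518). The alpha cell markers had a median of −0.108, with 3 of 4 lower (adjusted p = 0.791), and −0.065 without WT normal array 1 or WT high-fat array 1. The beta cell markers had a median of −0.057, with 5 of 7 lower (adjusted p = 0.804). None of these lists passed camera at its preset correlation.

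Markers of neurons and Schwann cells lay lower on the high-fat diet in both genotypes, by a median of −0.376 in WT (6 of 6 lower, adjusted p = 0.0761; −0.133 without WT normal array 3 and −0.569 without WT normal array 2) and −0.293 in KO (5 of 6 lower, adjusted p = 0.219; −0.192 without KO normal array 1), and neither passed. Genes of the cholesterol list lay higher on the high-fat diet by medians of 0.055 in WT (10 of 16 higher, adjusted p = 0.203) and 0.072 in KO (13 of 16 higher, adjusted p = 0.116). The pericyte gene Pdgfrb rose by 0.34 in KO over both diets (adjusted p = 0.0299) and Vil1, a microvillus protein whose gene lies among the neighbours of Sgpp2, fell by 0.28 (adjusted p = 0.0268); with same-numbered KO arrays as a random block (paired), neither passed.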
